A study of Homo sapiens with 8 samples.

How the data were processed

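RNA sequencing profiled SK-Hep1 cells, an established human cell line derived from a liver tumour and described as endothelial-like. Mock control cells and cells ectopically expressing SLC29A2, which encodes an equilibrative nucleoside transporter, each received a control treatment, sorafenib, dipyridamole, or both drugs. This gave 8 libraries, 1 for each of 8 conditions, in a full factorial layout of 3 factors. Doses and treatment times are not given in the sources used here. The control treatment is an interpretation of the labels of 2 libraries, whose descriptions name no drug and whose titles carry a short code. Per the labels, messenger RNA was selected by its poly(A) tail and libraries were made with a NEBNext Ultra RNA kit. No strand information is stated, so reads of overlapping genes on opposite strands cannot be told apart.

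The deposited values are FPKM, fragments per kilobase of gene model scaled to library size, with 1 table per library. The submitters' processing notes name TopHat2 2.0, HTSeq 0.6.1, edgeR and the build GRCh38.p12, without stating the role of each. Each table had 58310 lines, of which 8 held no gene identifier and 0 expression values, leaving 58302 genes. Of these, 31551 had a value above 0 in at least 1 library. Gene symbols, classes and positions came from GENCODE release 29 on GRCh38, which matched 58039 genes. FPKM multiplied by the mean transcript length of a gene fell on whole multiples of 1 step per library for 93.61% of values, at a tolerance of 0.01. Reads per gene were recovered from that step for 98.03% of expressed genes, and the recovered reads summed to between 100.79% and 100.85% of the library total that the step implied. The totals were 14.07 to 16.69 M reads per library. At that depth a single read in a gene of 2 kb corresponded to 0.03 to 0.0355 FPKM. These limits cover counting error only.

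Genes with a mean of at least 1 FPKM over the 8 libraries were kept, which left 13899. Values were transformed as log2(FPKM + 1), which compresses the changes of genes with low FPKM. Linear models were fitted with limma 3.58.1 in R 4.3.3, with moderated variances that followed a mean-variance trend, two-sided tests, and Benjamini-Hochberg adjustment over all genes tested at a threshold of 0.05. The additive model held cell type, sorafenib and dipyridamole, and each main effect was carried by 4 pairs of libraries that differed in that factor alone. Each interaction of a pair of factors was added to that model singly. No condition had a replicate, so the error term included both the spread between libraries and any interaction of the factors, and the p-values measured only the spread between these 8 libraries. The number of genes at least 2-fold apart on the log2(FPKM + 1) scale was counted between pairs of single libraries without a test. Correlations of log2 differences between library pairs were computed across genes, which are not independent replicates, without a p-value.

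Before the data were examined, 32 gene lists were fixed. They covered nucleoside transport and adenosine, purine and pyrimidine synthesis, cholesterol synthesis, fatty acid synthesis, ATF4 targets of the integrated stress response, endoplasmic reticulum chaperones, the heat shock response, ERK pathway output, cAMP and CREB targets, cyclic nucleotide phosphodiesterases, DNA replication, mitosis, p53 targets, apoptosis regulators, NRF2 targets, and iron handling and ferroptosis. They also covered hypoxia and glycolysis, nuclear genes of oxidative phosphorylation, mitochondrial genome transcripts, cytosolic ribosomal proteins, autophagy and lysosome, the interferon response, NF-kB and inflammatory genes, TGF-beta and YAP targets, mesenchymal genes, stem cell markers, drug efflux and uptake transporters, sorafenib-target receptor kinases and ligands, and markers of hepatocytes, endothelium, leukocytes and epithelium. Some genes belong to more than 1 list. The 30 lists with at least 5 measured members were tested with camera from limma at a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast. The hepatocyte list, with 4 measured members, and the leukocyte list, with 3, were counted but not tested. Each camera test was repeated with a correlation estimated from the residuals of the model. That repeat could lose a call even where the estimate lay below the preset value, so a lost call does not by itself point to correlated genes.

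The genes to be named were also fixed before the data were examined. For a main effect these were the 10 largest changes in each direction among genes past the threshold and changed the same way in all 4 library pairs. Where fewer than 5 genes qualified, the 5 largest with all 4 pairs at least 0.5 apart were named as values. For an interaction they were the 5 largest in each direction past the threshold or, where none passed, the 3 of each sign with the smallest p. SLC29A2 and the nucleoside list were always named, along with up to 4 members of each list and up to 3 genes per direction in each library pair. Genes known only by an identifier were counted and not named, and some genes that the rule names are not reported here.

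The alternatives tried were a pseudocount of 0.1, no filter on low values, a minimum of 5 FPKM, size factors by the median of ratios, rescaling to TPM, no mean-variance trend, a model with all pairwise interactions, a model with 4 separate treatments, and each library left out in turn. Further alternatives were chosen after the data were seen: voom from limma on the recovered reads, gene models under 200 nt left out, both dipyridamole-treated control-cell libraries left out, and size factors for the library pairs not planned with them. The model was tested on simulated data with known changes added to the spread between the libraries. It recovered 86.6% to 92.5% of changes of 2-fold in the main effects and 10.4% to 14.9% in the interactions, where changes of 4-fold were recovered at 83.3% to 89.4%. False calls were 13 of 169 for cell type, 13 of 166 for sorafenib, 11 of 168 for dipyridamole, 7 of 74 and 1 of 72 for the interactions of cell type with dipyridamole and sorafenib, and 7 of 69 for the interaction of the drugs. Among simulated lists, camera called 20 of 20 shifted by 0.7 on the log2 scale and 0 of 580 that were not shifted. The simulated genes were drawn independently of each other. These counts therefore do not cover lists whose members vary together, such as mitosis (estimated correlation 0.67 with dipyridamole).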

Results

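RNA sequencing measured messenger RNA in SK-Hep1 cells that were either mock control cells or cells carrying ectopic SLC29A2. Each cell type was given a control treatment, sorafenib, dipyridamole or both drugs, which made 8 libraries with 1 library per condition and no replicates. Sorafenib is an inhibitor of several kinases, among them RAF and the receptors of vascular endothelial growth factor, and dipyridamole inhibits nucleoside transport and phosphodiesterases. The control-cell libraries held 16.69 M reads with the control treatment, 15.61 M with sorafenib, 14.07 M with dipyridamole and 14.97 M with both drugs. In SLC29A2 cells the totals were 15.38, 14.49, 16.19 and 16.5 M reads in the same order.

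The control-cell libraries given dipyridamole differed from the other 6 in composition. Non-coding genes took 2.51% of reads with dipyridamole and 2.72% with both drugs in control cells, against 1.62% to 1.96% in the other libraries. The number of genes above 0 FPKM was 23766 and 24801 in those libraries and 22613 to 23514 in the others. Mitochondrial transcripts took from 1.9% of reads, in control cells given both drugs, to 5.81%, in control cells given dipyridamole alone. The first 3 principal components held 52.8%, 17% and 12.3% of the variance, and the third set the dipyridamole-treated libraries of control cells (15.9 and 23.1) apart from those of SLC29A2 cells (-20.5 and -24.9).

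The question of the comparison between cell types was what ectopic SLC29A2 changed across treatments. SLC29A2 itself (ENSG00000174669; GRCh38 chromosome 11, 66362521 to 66372214, minus strand) rose from 7.56 ± 0.317 FPKM in control cells to 2149 ± 650.6 FPKM in SLC29A2 cells (SD, n = 4 libraries each). The log2 fold change was 7.93 ± 0.18 (SE; limma adjusted p = 8.4e-08), and the 4 library pairs ranged from 7.39 to 8.55. No other gene passed the threshold, with 546 genes at an unadjusted p under 0.05 against 695 that chance would give, and voom called SLC29A2 alone as well. Without the SLC29A2 library given sorafenib, 2 genes passed. The largest differences seen in all 4 pairs, none of them past the threshold, were 1.10 ± 0.32 for the chemokine gene CCL3L3 (adjusted p = 0.965), 1.07 ± 0.15 for KISS1 (0.463), -1.28 ± 0.21 for the keratin gene KRT39 (0.604), -0.96 ± 0.17 for IGFBP7, -0.85 ± 0.25 for MFAP5 and -0.84 ± 0.21 for MCC (0.965 each). The other 3 genes that the rule named were the small RNA genes SNORD93 (1.2), MIR8078 (0.92) and RNU7-123P (-1.17), which rested on few reads.

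Other genes of nucleoside handling were compared between the cell types. Of the 15 measured members of the nucleoside transport and adenosine list, SLC29A2 rose and the other 14 did not pass, with the same counts adjusted over the list alone. The transporter genes SLC29A1 (0.16 ± 0.13), SLC29A3 (-0.05 ± 0.16) and SLC29A4 (-0.12 ± 0.19), the adenosine receptor genes ADORA1 (-0.02 ± 0.20) and ADORA2B (0.10 ± 0.14) and the ectonucleotidase genes NT5E (-0.05 ± 0.24) and ENTPD1 (-0.06 ± 0.18) did not pass. Values for the enzymes were -0.18 ± 0.13 for ADA, -0.02 ± 0.09 for ADK, -0.09 ± 0.22 for DCK, 0.28 ± 0.24 for TK1, -0.24 ± 0.17 for TK2, 0.06 ± 0.13 for PNP and -0.08 ± 0.19 for CDA. With a library left out TK1 ran from -0.02 to 0.51 and NT5E from -0.3 to 0.18. In simulated data 41.8% of changes of 1.5-fold between cell types were recovered, so smaller differences are not excluded. The list passed the camera test upward (adjusted p = 0.0309; adjusted p = 0.799 with an estimated correlation), although its median was -0.05 and its mean 0.51, since the ectopic gene is 1 of its members. A further 6 lists passed with median differences of at most 0.12 in size and 0 members past the threshold: mitosis, heat shock, endoplasmic reticulum chaperones and mitochondrial transcripts upward (adjusted p = 0.00164, 0.016, 0.0309 and 0.0338; each adjusted p = 0.863 with an estimated correlation), and mesenchymal genes and fatty acid synthesis downward (0.0338 and 0.0343; adjusted p = 0.863 and 0.799 with an estimated correlation). Adjusted over the list alone, 1 mesenchymal gene and 1 fatty acid gene fell and 0 members of the other 4 passed. Each of the 7 calls was lost or turned with at least 1 library left out.

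Agreement between library pairs differed by factor. Across genes, the log2 differences between cell types in separate library pairs correlated with a median Pearson r of -0.089 (-0.23 to 0.435, 6 correlations). The medians were 0.381 for sorafenib (0.335 to 0.665) and 0.612 for dipyridamole (0.382 to 0.652). In single library pairs, 147 genes were at least 2-fold apart between the cell types under the control treatment, 154 under sorafenib, 241 under dipyridamole and 538 under both drugs, and 203 of the 241 and 492 of the 538 were lower in SLC29A2 cells. The median differences over all genes in the last 2 pairs were -0.102 and -0.148. With size factors 218 and 321 genes were at least 2-fold apart there, 162 and 246 of them lower.

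Sorafenib was compared with its absence to ask which genes respond to this kinase inhibitor in both cell types. The largest falls were in SERPINB2, an inhibitor of plasminogen activators, from a mean of 114.8 to 7.93 FPKM (log2 fold change -3.50 ± 0.36 SE, n = 4 pairs), and in the growth-factor-induced transcription factor gene EGR1, from 24.4 to 1.77 FPKM (-3.17 ± 0.24). ANGPTL4, which encodes an inhibitor of lipoprotein lipase, fell by 2.47 ± 0.13, the cytokine gene IL24 by 2.38 ± 0.36, and PLAT, which encodes tissue plasminogen activator, by 2.08 ± 0.20, from 1067 to 298.1 FPKM. G0S2 (-1.98 ± 0.21), the chemokine gene CXCL8 (-1.83 ± 0.25), the endothelial gene ESM1 (-1.82 ± 0.17), C11orf91 (-2.01 ± 0.39) and MIR3649 (-2.18 ± 0.40, on 11 reads or fewer per library) also fell. Among rises were CLU, the gene of the chaperone clusterin, from 4.39 to 20.5 FPKM (2.02 ± 0.21), the immunoproteasome gene PSMB9 (1.72 ± 0.19), UBA7, which encodes the activating enzyme for ISG15 (1.6 ± 0.14), the phosphatase gene DUSP8 (1.82 ± 0.18), ANKRD2 (1.99 ± 0.20), ARVCF (1.95 ± 0.23), ABLIM1 (1.59 ± 0.22), LINC01583 (1.75 ± 0.25), the antisense transcript CHILL1 (2.37 ± 0.36) and KCP (2.39 ± 0.51). CHILL1 was 3.3 and 3.25 higher on the log2 scale with both drugs than with dipyridamole alone, in control and SLC29A2 cells. In control cells KCP went from 0.718 to 2.74 FPKM with sorafenib alone and from 8.3 to 130.1 FPKM where dipyridamole was also given. KCP (GRCh38 chromosome 7, 128862451 to 128910719, minus strand) overlaps genes on the other strand, and its call was lost without the control-cell dipyridamole library (adjusted p = 0.106). The calls of C11orf91 and MIR3649 were lost without the same library (0.0865 and 0.0809). Without both dipyridamole-treated control-cell libraries CHILL1 (0.0701) and ABLIM1 (0.0593) lost theirs, as did KCP (0.139), C11orf91 (0.123) and MIR3649 (0.0965).

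With limma, 1127 genes passed the threshold for sorafenib, 825 higher and 302 lower, all of them in the same direction in all 4 library pairs, and 106 and 88 of them changed at least 2-fold. The adjusted p of the genes named in the previous paragraph ran from 2.2e-04 for ANGPTL4 to 0.0278 for KCP. The count fell to 449 without the control-cell library given sorafenib, to 272 without that given dipyridamole and to 300 without that given both drugs. It fell to 609 without the SLC29A2-cell library given the control treatment, to 323 without that given dipyridamole and to 464 without that given both drugs. It was 136 with no filter on low values, 4839 with all pairwise interactions in the model, 1755 with 4 separate treatments and 301 without both dipyridamole-treated control-cell libraries. The share of calls that were higher was 73.2%, and 47.6% with size factors, which moved the median effect of all genes from 0.089 to -0.019; 738 calls were shared in direction. Of 91 called genes named here by the rule, 44 kept their call with each library left out and 47 lost it at least once.

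Some genes downstream of growth-factor signalling fell with sorafenib. Of 23 measured genes of ERK pathway output, 12 fell and 0 rose (16 fell adjusted over the list alone), and the list fell in the camera test (adjusted p = 1.4e-14; adjusted p = 0.232 with an estimated correlation). Besides EGR1, the immediate-early gene FOS fell by 1.75 ± 0.18 (limma adjusted p = 0.0025), and the feedback regulators DUSP6 and SPRY4 by 1.54 ± 0.18 (0.00332) and 1.11 ± 0.18 (0.0118). As few as 3 members fell with a library left out, that of control cells given both drugs, and SPRY4 lost its call without the control-cell dipyridamole library (adjusted p = 0.0567). Where 1 library is named for a lost call of a gene, its omission gave the highest adjusted p. Other omissions may also have ended the call.

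Some genes of DNA replication also fell with sorafenib. Of 25 genes 7 fell (9 adjusted over the list alone; camera adjusted p = 2.4e-10; adjusted p = 0.232 with an estimated correlation), among them RRM2, a subunit of ribonucleotide reductase (-1.2 ± 0.10), UHRF1 (-0.88 ± 0.14), the helicase gene MCM7 (-0.58 ± 0.10) and the transcription factor gene E2F1 (-0.61 ± 0.11). As few as 2 fell without the control-cell sorafenib library, and MCM7 and E2F1 lost their calls without the control cells given both drugs (adjusted p = 0.0628) and given dipyridamole (0.0634). Of 25 mitosis genes 0 passed in limma (0 adjusted over the list alone; camera adjusted p = 0.0923). In the purine and pyrimidine synthesis list, RRM2 and CTPS1 (-0.49 ± 0.13) fell and CTPS2 (0.52 ± 0.12) rose among 25 members (4 fell and 1 rose adjusted over the list alone), with a camera adjusted p of 0.00463 (adjusted p = 0.232 with an estimated correlation). CTPS1 lost its call in 7 of the 8 refits with a library left out (adjusted p up to 0.157) and CTPS2 in all 8 (up to 0.112).

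Some lipid synthesis genes fell with sorafenib. Of 24 cholesterol synthesis genes 6 fell (8 adjusted over the list alone; camera adjusted p = 4.3e-09; adjusted p = 0.232 with an estimated correlation), including INSIG1, a sterol sensor of the endoplasmic reticulum (-1.63 ± 0.15), EBP (-0.56 ± 0.10) and MSMO1 (-0.49 ± 0.10). Of 16 fatty acid synthesis genes 4 fell (7 adjusted over the list alone; camera adjusted p = 2.0e-05; adjusted p = 0.232 with an estimated correlation). These were FASN, fatty acid synthase, from 1112 to 553 FPKM (-0.97 ± 0.20), the desaturase gene SCD (-0.98 ± 0.22) and the elongase genes ELOVL6 (-0.77 ± 0.16) and ELOVL5 (-0.53 ± 0.14). As few as 2 cholesterol genes fell without the control-cell sorafenib library, where EBP lost its call (adjusted p = 0.0601), and 0 fatty acid genes without the control cells given both drugs, where FASN (0.0968) and ELOVL5 (0.129) lost theirs. Of the 8 refits with a library left out, MSMO1 lost its call in all 8 (adjusted p up to 0.084), ELOVL5 in 6, ELOVL6 in 5 (up to 0.0907) and SCD in 4 (up to 0.107).

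Some transcripts of the mitochondrial genome and some genes of hypoxia and glycolysis fell with sorafenib. Of 13 mitochondrial transcripts 7 fell (13 adjusted over the list alone; camera adjusted p = 2.5e-11; adjusted p = 0.275 with an estimated correlation), among them MT-CO2 from 6536 to 3108 FPKM (-1.13 ± 0.26), MT-ND2 (-1 ± 0.23), MT-ATP8 (-0.90 ± 0.21) and MT-CYB (-0.87 ± 0.17). Of these transcripts 0 passed without the control-cell sorafenib library; the highest adjusted p with a library left out was 0.121, 0.117, 0.117 and 0.0871 in that order. The calls were lost in 6, 6, 7 and 5 of the 8 refits. Of 23 hypoxia and glycolysis genes 5 fell (6 fell and 1 rose adjusted over the list alone; camera adjusted p = 1.6e-04; adjusted p = 0.275 with an estimated correlation), including lactate dehydrogenase LDHA (-0.93 ± 0.13) and the glucose transporter SLC2A1 (-0.68 ± 0.11). As few as 1 fell without the control cells given both drugs, where SLC2A1 lost its call (0.0563). Of 27 nuclear genes of oxidative phosphorylation, ATP5MC1 fell (-0.48 ± 0.12; 0 adjusted over the list alone), with a camera adjusted p of 0.0394 (adjusted p = 0.546 with an estimated correlation). Both calls were lost without the SLC29A2 cells given dipyridamole (0.131 for ATP5MC1, which lost its call in 6 of the 8 refits, and 0.237 for the list).

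The lists of ATF4 targets, p53 targets and interferon genes were higher with sorafenib in camera. Of 32 ATF4 targets, genes of amino acid supply and the integrated stress response, 14 rose (21 rose and 1 fell adjusted over the list alone; camera adjusted p = 1.7e-06; adjusted p = 0.394 with an estimated correlation). The examples were AARS1, alanyl-tRNA synthetase, from 314.5 to 650.4 FPKM (1.06 ± 0.15), NUPR1 (1.55 ± 0.22), JDP2 (1.38 ± 0.19) and CEBPG (0.75 ± 0.12). Of 23 p53 targets 11 rose (15 adjusted over the list alone; camera adjusted p = 4.2e-07; adjusted p = 0.232 with an estimated correlation), including the pro-apoptotic gene BBC3 (1.18 ± 0.11), BTG2 (1.04 ± 0.15), PHLDA3 (1.10 ± 0.17) and GADD45A, a growth-arrest gene, from 778.8 to 1439 FPKM (0.93 ± 0.14). Of 19 interferon-response genes 4 rose (7 adjusted over the list alone; camera adjusted p = 0.00402; adjusted p = 0.275 with an estimated correlation), namely PSMB9, the RNA sensor IFIH1 (0.86 ± 0.13), OAS3 (0.62 ± 0.13) and MX1 (0.83 ± 0.21). As few as 8 ATF4 targets rose without the control-cell sorafenib library, 4 p53 targets without the control cells given both drugs, and 2 interferon genes without the control cells given dipyridamole. OAS3 lost its call in 6 of the 8 refits with a library left out (adjusted p up to 0.0905) and MX1 in 7 (up to 0.13).

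Some stem cell markers fell with sorafenib, and NF-kB genes and TGF-beta and YAP targets moved both ways. Of 11 stem cell markers 3 fell (4 adjusted over the list alone; camera adjusted p = 0.0109; adjusted p = 0.232 with an estimated correlation): the aminopeptidase gene ANPEP from 1666 to 604.5 FPKM (-1.49 ± 0.15), ALDH1A3 (-0.95 ± 0.13) and SOX9 (-0.86 ± 0.19), which lost its call in 6 of the 8 refits with a library left out (adjusted p up to 0.0827). Of 17 NF-kB and inflammatory genes 4 rose and 2 fell (5 and 8 adjusted over the list alone; camera adjusted p = 0.15), with ICAM1 (0.95 ± 0.12), RELB (0.83 ± 0.14) and SOD2 (0.69 ± 0.12) rising beside the fall of CXCL8; SOD2 lost its call without the control cells given dipyridamole (0.0634), where 2 rose and 1 fell. Of these genes 6 fell without the control cells given the control treatment. Of 18 TGF-beta and YAP targets 3 rose and 3 fell (4 and 5 adjusted over the list alone; camera adjusted p = 0.33), with TGFB2 rising by 1.27 ± 0.15 and F3, the tissue factor gene (-1.68 ± 0.23), CCN2 (-1.73 ± 0.28) and THBS1 (-1.03 ± 0.19) falling. CCN2 lost its call without the SLC29A2 cells given dipyridamole (0.0557), where 1 fell, and THBS1 without the control cells given both drugs (0.0652). In the nucleoside list SLC29A1 (-0.72 ± 0.13, limma adjusted p = 0.0179) and PNP (-0.70 ± 0.13, 0.0202) fell among 15 members (3 fell and 1 rose adjusted over the list alone; camera adjusted p = 0.364; median 0.12, mean -0.02). Their calls were lost without the control cells given both drugs (0.0676) and given dipyridamole (0.0808), and SLC29A2 (0.23 ± 0.18, 0.447) and NT5E (-0.91 ± 0.24, 0.0514) did not pass.

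The remaining lists had few members past the threshold for sorafenib and did not pass in camera. In brackets are the counts that rose and fell adjusted over the list alone and the camera adjusted p. Of 14 cAMP and CREB targets 2 rose and 2 fell (2 and 4; 0.0568), of 22 apoptosis regulators 3 and 1 (5 and 1; 0.33), of 11 epithelial markers 3 and 1 (3 and 1; 0.88), and of 10 transporters 1 and 1 (1 and 1; 0.604). Of 18 NRF2 targets 2 rose (3 and 1; 0.643), of 24 lysosome genes 2 (3 and 0; 0.71), of 20 mesenchymal genes 2 (2 and 0; 0.668), of 17 iron genes 1 (1 and 0; 0.882) and of 16 receptor kinases and ligands 1 (1 and 0; 0.33). In limma 0 passed among 20 endoplasmic reticulum chaperones (0 and 0; 0.364), 11 phosphodiesterases (0 and 0; 0.527), 30 ribosomal proteins (0 and 0; 0.761), 5 endothelial markers (0 and 0; 0.0927) and 15 heat shock genes (2 and 1; 0.604). Of 4 hepatocyte markers 1 rose (1 and 0) and of 3 leukocyte markers 1 fell (1 and 1), neither list being tested. The camera direction was down for heat shock genes (median 0.03, mean 0.12) and ribosomal proteins (0.09, 0.06). It was also down for chaperones (-0.02, 0.01), phosphodiesterases (-0.04, 0.03) and mesenchymal genes (-0.03, 0.06), and up for epithelial markers (-0.02, 0.11).

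Examples from those lists that kept their calls with each library left out were the phosphatase gene DUSP1 (-0.74 ± 0.11), the keratin gene KRT7 (0.93 ± 0.15), the transporter gene SLCO4A1 (-1.39 ± 0.20), SERPINA1, which encodes alpha-1 antitrypsin (0.87 ± 0.14), and HLA-DRA (-0.84 ± 0.13). Without both dipyridamole-treated control-cell libraries SLCO4A1 (0.0671) and SERPINA1 (0.0504) lost their calls. Other counts fell with a library left out. The rises fell to 0 for cAMP targets and 1 for epithelial markers without the control cells given dipyridamole. They fell to 1 for apoptosis regulators and 0 for transporters without the control cells given sorafenib, and to 0 for NRF2 targets and mesenchymal genes without the control cells given both drugs. For lysosome genes, 0 rose in each such refit, and 0 iron genes and 0 receptor kinases and ligands rose without the control cells given the control treatment. Of the TGF-beta and YAP targets, 1 rose without the control cells given sorafenib, and of the cAMP targets 1 fell without those given both drugs.

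Leaving out both dipyridamole-treated control-cell libraries, which leaves fewer libraries by construction, ended further sorafenib calls given in the preceding paragraphs. The adjusted p was 0.0862 for SPRY4, 0.0678 for UHRF1, 0.144 for CTPS1, 0.0914 for CTPS2, 0.0938 for PNP and 0.0665 for CCN2. Among lipid genes it was 0.0589 for EBP, 0.0707 for MSMO1, 0.0591 for SCD, 0.0982 for ELOVL6 and 0.0792 for ELOVL5. It was 0.0719 for MT-CO2, 0.126 for MT-ATP8, 0.0671 for SLC2A1 and 0.0944 for ATP5MC1, and 0.0554 for NUPR1, 0.0535 for PHLDA3, 0.0512 for OAS3 and 0.129 for MX1. With size factors CTPS1 (0.0502), CTPS2 (0.0614) and OAS3 (0.073) did not pass. With them 8 ATF4 targets, 1 apoptosis regulator, 0 NRF2 targets, 0 lysosome genes, 0 iron genes, 0 receptor kinases and ligands and 0 transporters rose, while 4 cAMP targets fell.

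**Figure D1:**
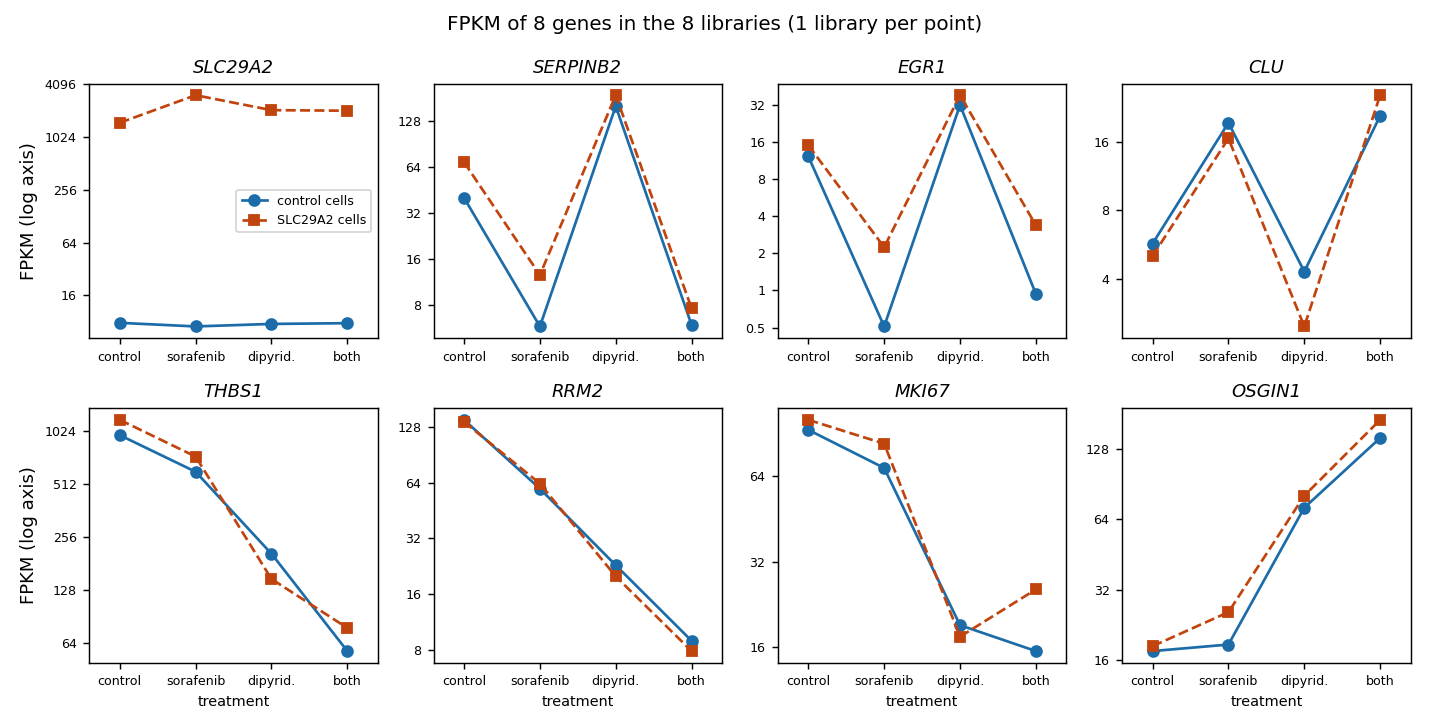
FPKM on a log axis of named genes in each of the 8 libraries, by treatment, with control cells as circles and SLC29A2 cells as squares, and 1 library per point. SLC29A2 lay between 7.11 and 7.81 FPKM in control cells and between 1477 and 3040 FPKM in SLC29A2 cells.

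Dipyridamole was compared with its absence to ask what this transport inhibitor changes in both cell types. Genes of cell division were among those that fell. THBS1, the matrix protein thrombospondin, fell from a mean of 874.6 to 122.1 FPKM (log2 fold change -2.96 ± 0.19 SE, n = 4 pairs), RRM2 from 99.6 to 14.9 FPKM (-2.68 ± 0.10), the mitotic kinesin gene KIF20A from 69.8 to 12 FPKM (-2.45 ± 0.11) and the proliferation marker gene MKI67 from 86.5 to 19.4 FPKM (-2.11 ± 0.15). LMNB1, which encodes lamin B1 (-2.31 ± 0.11), the cytokinesis gene ANLN (-2.06 ± 0.10), CDCA3 (-2.06 ± 0.11), CAVIN2 (-2.22 ± 0.15), the connexin gene GJA5 (-2.07 ± 0.17) and a Y RNA on few reads (-2.13 ± 0.30) also fell. Rises included OSGIN1, an oxidative-stress-induced gene, from 20 to 116.4 FPKM (2.40 ± 0.16), the heat shock gene HSPA6 (2.38 ± 0.36), TM4SF19 (2.62 ± 0.21), the incretin receptor gene GIPR (2.36 ± 0.26), BEX2 (2.20 ± 0.15) and KCP (3.43 ± 0.51). Non-coding RNAs were among them: the pseudogene RPLP0P2 (3.49 ± 0.12), which shares sequence with its parent gene, LINC-PINT (2.80 ± 0.35), SMYD3-IT1, which lies in an intron of SMYD3 (2.47 ± 0.22), and LINC02154 (2.37 ± 0.13). KCP changed unevenly, in control cells from 0.718 to 8.3 FPKM without sorafenib and from 2.74 to 130.1 FPKM with it.

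With limma, 4173 genes passed the threshold for dipyridamole, 2428 higher and 1745 lower, and 429 and 345 of them changed at least 2-fold. The direction was the same in all 4 library pairs for 4030 of the 4173. The adjusted p of the genes named in the previous paragraph ran from 3.0e-06 for RPLP0P2 to 0.00174 for HSPA6, and each of them kept its call with each library left out. The count was 7411 with all pairwise interactions in the model and 2622 with no filter on low values. The share of calls that were higher was 58.2%, but 44.7% with size factors and 47.9% without both dipyridamole-treated control-cell libraries. Of 124 called genes named by the rule, 103 kept their call with each library left out.

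The cell cycle lists fell with dipyridamole as a whole. All 25 measured mitosis genes fell (25 adjusted over the list alone; camera adjusted p = 9.2e-26; adjusted p = 0.399 with an estimated correlation), among them the checkpoint kinase genes BUB1 (-1.86 ± 0.11) and BUB1B (-1.66 ± 0.10) and the cyclin gene CCNB1 from 206.6 to 62.2 FPKM (-1.71 ± 0.10). All 25 DNA replication genes fell (25 adjusted over the list alone; camera adjusted p = 2.0e-21; adjusted p = 0.251 with an estimated correlation), with MCM7 (-1.54 ± 0.10), MCM4 (-1.89 ± 0.13) and the polymerase clamp gene PCNA (-1.68 ± 0.11) as examples beside RRM2. Limma adjusted p-values of these examples were at most 4.7e-05. With 1 library left out, all 25 mitosis genes and at least 22 replication genes still fell, and with size factors all 25 of each. Of 25 purine and pyrimidine synthesis genes 15 fell and 1 rose (16 and 1 adjusted over the list alone; camera adjusted p = 1.2e-07; adjusted p = 0.126 with an estimated correlation), including thymidylate synthase TYMS (-1.41 ± 0.13), RRM1 (-1.17 ± 0.12) and CTP synthase CTPS1 (-1.11 ± 0.13).

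In the nucleoside list, 5 genes fell and 1 rose with dipyridamole among 15 members (5 fell and 3 rose adjusted over the list alone; camera adjusted p = 0.0507). The falls were in the adenosine receptor gene ADORA1 (-1.39 ± 0.20, limma adjusted p = 0.0014), the transporter gene SLC29A1 (-0.81 ± 0.13, 0.0024), thymidine kinase TK1 (-1.10 ± 0.24, 0.01), adenosine kinase ADK (-0.40 ± 0.09, 0.012) and the ectonucleotidase NT5E (-0.79 ± 0.24, 0.0357), and cytidine deaminase CDA rose (0.68 ± 0.19, 0.026). NT5E lost its call in 5 of the 8 refits with a library left out (adjusted p up to 0.106), and CDA without the SLC29A2 cells given the control treatment (0.0797) and with size factors (0.0808). Without both dipyridamole-treated control-cell libraries TK1 (0.174) and ADK (0.0509) lost theirs. SLC29A2 itself (-0.01 ± 0.18, 0.974), SLC29A4 (0.56 ± 0.19, 0.0503) and ADORA2B (0.42 ± 0.14, 0.054) did not pass.

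The lists of ATF4 targets, autophagy and lysosome, cAMP and CREB targets and NF-kB genes were higher with dipyridamole in camera. Of 32 ATF4 targets 21 rose (22 adjusted over the list alone; camera adjusted p = 9.6e-07; adjusted p = 0.399 with an estimated correlation), including DDIT3, which encodes the stress transcription factor CHOP (1.90 ± 0.15), TRIB3 (1.79 ± 0.19), CEBPB (1.30 ± 0.15) and NUPR1 (1.49 ± 0.22). Of 24 autophagy and lysosome genes 8 rose and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 0.00318; adjusted p = 0.399 with an estimated correlation), with the autophagosome gene MAP1LC3B (1.21 ± 0.09), the lysosomal cholesterol exporter NPC1 (1.41 ± 0.12), WIPI1 (1.27 ± 0.11) and the autophagy receptor SQSTM1 from 215.2 to 530 FPKM (1.29 ± 0.12). Of 14 cAMP and CREB targets 8 rose (11 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.0124; adjusted p = 0.399 with an estimated correlation), among them CREB5 (1.53 ± 0.23), ATF3 (1.39 ± 0.26), NR4A1 (0.73 ± 0.14) and MAFF (0.63 ± 0.13); 5 rose without the control cells given the control treatment. Of 17 NF-kB and inflammatory genes 9 rose (9 adjusted over the list alone; camera adjusted p = 0.0254; adjusted p = 0.646 with an estimated correlation), with CXCL2 (2.07 ± 0.32), RELB (1.22 ± 0.14), ICAM1 (0.82 ± 0.12) and LIF (0.61 ± 0.15). Only 4 rose without the control cells given the control treatment, the camera call was lost without the SLC29A2 cells given dipyridamole (0.112), and LIF lost its call without the control cells given both drugs (0.0518).

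The lists of cholesterol synthesis, TGF-beta and YAP targets, oxidative phosphorylation and mitochondrial transcripts were lower with dipyridamole in camera. Of 24 cholesterol synthesis genes 9 fell (10 fell and 2 rose adjusted over the list alone; camera adjusted p = 0.00327; adjusted p = 0.399 with an estimated correlation), among them EBP (-0.78 ± 0.10), IDI1 (-0.80 ± 0.13) and ACAT2 (-1.02 ± 0.17). Of 18 TGF-beta and YAP targets 9 fell and 3 rose (9 and 3 adjusted over the list alone; camera adjusted p = 0.0124; adjusted p = 0.399 with an estimated correlation), with THBS1, F3 (-1.42 ± 0.23), TGFB2 (-0.89 ± 0.15) and CCN2 (-1.69 ± 0.28) falling; the camera call was lost without the control cells given both drugs (0.0517) and with size factors (0.0511). Of 27 nuclear genes of oxidative phosphorylation 6 fell (6 adjusted over the list alone; camera adjusted p = 0.00456; adjusted p = 0.399 with an estimated correlation), including SDHA (-0.53 ± 0.10), and 2 fell without the control-cell sorafenib library. Of 13 mitochondrial transcripts 0 passed (0 adjusted over the list alone), but the list fell in camera (adjusted p = 0.0412; adjusted p = 0.909 with an estimated correlation). That call was lost with size factors (0.0999) and without the control cells given both drugs (0.294), and 10 transcripts fell without the control cells given dipyridamole, where their median difference was 0.46 against -0.44 in SLC29A2 cells given dipyridamole.

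Several lists held genes that moved both ways with dipyridamole and did not pass in camera. Of 23 hypoxia and glycolysis genes 8 rose and 7 fell (8 and 7 adjusted over the list alone; camera adjusted p = 0.681), with the glucose transporter SLC2A3 (1.21 ± 0.11), NDRG1 (1.24 ± 0.16) and P4HA2 (1.01 ± 0.13) rising and LDHA falling by 1.26 ± 0.13. As few as 5 rose without the control cells given sorafenib and 4 fell without those given both drugs. Of 20 endoplasmic reticulum chaperone genes 5 rose and 4 fell (5 and 6 adjusted over the list alone; camera adjusted p = 0.42), HERPUD1 (0.79 ± 0.12) and HSPA5 (0.81 ± 0.20) rising and the disulfide isomerase genes PDIA4 (-0.75 ± 0.13) and PDIA6 (-0.54 ± 0.11) falling. HSPA5 lost its call without the control cells given both drugs (0.0525), where 2 rose, and 2 fell without the SLC29A2 cells given the control treatment. Of 23 p53 targets 6 rose and 3 fell (6 and 3 adjusted over the list alone; camera adjusted p = 0.42), with GADD45A (1.54 ± 0.14), BBC3 (1.05 ± 0.11), PHLDA3 (1.05 ± 0.17) and SESN2 (1.31 ± 0.24) rising. Of 15 heat shock genes 2 rose and 4 fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.61; median -0.08, mean 0.08), the near-identical genes HSPA1A (1.02 ± 0.30) and HSPA1B (1.2 ± 0.35) rising, with calls lost without the control cells given both drugs (0.103 and 0.104). The main effect of HSPA1B came mostly from the libraries given both drugs. HSPA1B was at 30.4 FPKM with the control treatment, 31 with dipyridamole and 96.6 with both drugs in control cells. In SLC29A2 cells it was at 29.9, 38.7 and 121.4 FPKM. HSP90AB1 fell by 0.53 ± 0.12, and 1 heat shock gene fell without the control cells given the control treatment. Of 23 ERK output genes 4 rose and 3 fell (4 and 3 adjusted over the list alone; camera adjusted p = 0.837), with DUSP5 rising by 0.80 ± 0.18 and CCND1, the gene of cyclin D1, falling by 0.59 ± 0.12; 1 rose without the control cells given dipyridamole.

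The other lists did not pass in camera for dipyridamole, and the brackets again hold the counts that rose and fell adjusted over the list alone and the camera adjusted p. Of 16 fatty acid synthesis genes 2 rose and 4 fell (2 and 6; 0.0507), with TMEM97 falling by 1.43 ± 0.21 and ACSS2 rising by 0.66 ± 0.10. Of 19 interferon genes 2 rose and 4 fell (3 and 6; 0.373), with IFIT1 (-1.27 ± 0.16) and IFIT3 (-0.68 ± 0.15) falling and IRF7, an interferon regulatory factor gene (0.90 ± 0.15), rising. Of 20 mesenchymal genes 3 rose and 5 fell (3 and 6; 0.376), including the collagen gene COL3A1 (-1.23 ± 0.27) and the collagen cross-linking gene LOXL2 (-0.75 ± 0.12). Of 11 stem cell markers 3 rose and 3 fell (4 and 5; 0.688; median 0.16, mean -0.07), with THY1 falling by 1.22 ± 0.13. Of 16 receptor kinases and ligands 3 rose and 5 fell (4 and 5; 0.837; median 0.03, mean -0.01), with the receptor gene KIT falling by 1.64 ± 0.18 and FGFR1 (0.77 ± 0.11) and the angiogenic factor gene VEGFA (0.74 ± 0.14) rising. Of 22 apoptosis regulators 3 rose and 1 fell (3 and 0; 0.782), of 10 transporters 1 and 1 (1 and 1; 0.514), and of 11 epithelial markers 2 and 2 (2 and 2; 0.42). In limma 0 of 30 ribosomal protein genes passed (0 and 0; 0.183). Of 5 endothelial markers 1 rose (1 and 0; 0.839), of 4 hepatocyte markers 1 rose (1 and 0) and of 3 leukocyte markers 2 fell (0 and 3), the last 2 lists being too short to test.

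Some of these counts moved with size factors or with a library left out. With size factors 10 oxidative phosphorylation genes, 7 interferon genes and 5 stem cell markers fell, while 5 cAMP targets, 1 mesenchymal gene and 0 hepatocyte markers rose, and 2 apoptosis regulators and 2 transporters fell. Without the control cells given sorafenib 2 interferon genes fell, 0 transporters passed and 0 endothelial markers rose. Without the control cells given both drugs 0 mesenchymal genes rose, and without the SLC29A2 cells given sorafenib 2 mesenchymal genes and 2 receptor kinases and ligands fell. Without the control cells given the control treatment 1 interferon gene and 1 epithelial marker rose, 0 hepatocyte markers rose and 0 apoptosis regulators fell. Without those given both drugs 1 fatty acid gene rose and 1 leukocyte marker fell. The endothelial gene ROBO4 lost its call without the control cells given both drugs (0.0887). Without both dipyridamole-treated control-cell libraries the calls of ATF3 (0.0743), LIF (0.197), SDHA (0.0577), CCND1 (0.0605), VEGFA (0.0914), COL3A1 (0.0986), HSPA5 (0.116), HSPA1A (0.0994), HSPA1B (0.133) and ROBO4 (0.0828) were lost.

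Sorafenib and dipyridamole were compared to ask whether they changed the same genes. Of the genes past the threshold, 472 were higher with each drug against 144 from independent lists, 148 were lower with each against 38, and 53 moved in opposite directions against 156. With size factors 232 were higher with each against 59 and 273 were lower with each against 81, so that shared rises no longer outnumbered shared falls. RRM2, LDHA, F3 and CCN2 fell with each drug, NUPR1, BBC3, GADD45A and ICAM1 rose with each, and TGFB2 rose with sorafenib and fell with dipyridamole. Across genes the log2 effects correlated with r = 0.452, where the genes are not independent replicates.

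**Figure D2:**
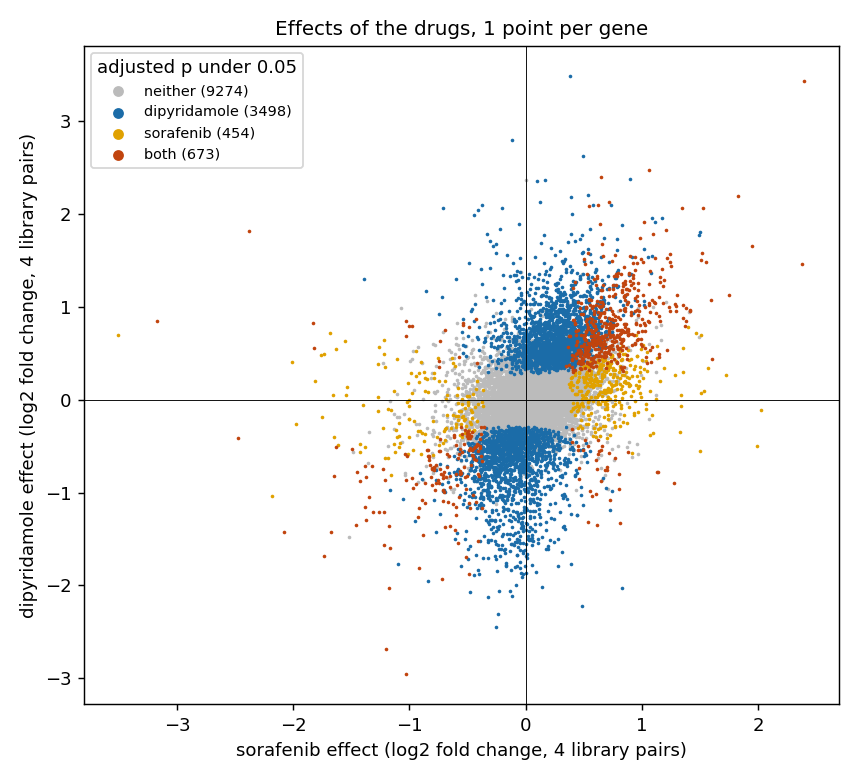
Log2 fold change of each of 13899 genes with sorafenib (horizontal) and with dipyridamole (vertical), coloured by which of the limma tests it passed. Of these genes 673 passed both, 454 passed sorafenib alone, 3498 passed dipyridamole alone and 9274 passed neither.

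The combination was compared with the control treatment and with each drug alone to describe what both drugs gave together. These comparisons set 1 library against 1 and have no test. In control cells 329 genes were at least 2-fold apart from the control treatment with sorafenib, 1195 with dipyridamole and 2660 with both drugs, and in SLC29A2 cells 304, 1274 and 2477. Of the 2660 in control cells 1980 were higher, in a library whose median difference over all genes was 0.251, and of the 2477 in SLC29A2 cells 1391 were higher. With size factors the excess of higher genes turned, to 1098 higher and 1231 lower in control cells and 1194 higher and 1273 lower in SLC29A2 cells. With both drugs in control cells KCP was at 130.1 FPKM against 0.718, DUSP8 at 53.5 against 2.18, RRM2 at 8.96 against 139.7, THBS1 at 57.4 against 972.8 and PLAT at 124.6 against 1492. In SLC29A2 cells KCP was at 98.4 against 1.35 FPKM, CHILL1 at 17.3 against 0.139, RRM2 at 7.88 against 136.3 and THBS1 at 77.8 against 1189. Both drugs against sorafenib alone gave 1524 genes in control cells and 1531 in SLC29A2 cells, and against dipyridamole alone 845 and 877; with size factors these were 1298, 1503, 680 and 852. Clusterin CLU was 2.93 higher on the log2 scale with both drugs than with dipyridamole alone in SLC29A2 cells, where SERPINB2 was at 7.55 against 189.5 FPKM.

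**Figure D3:**
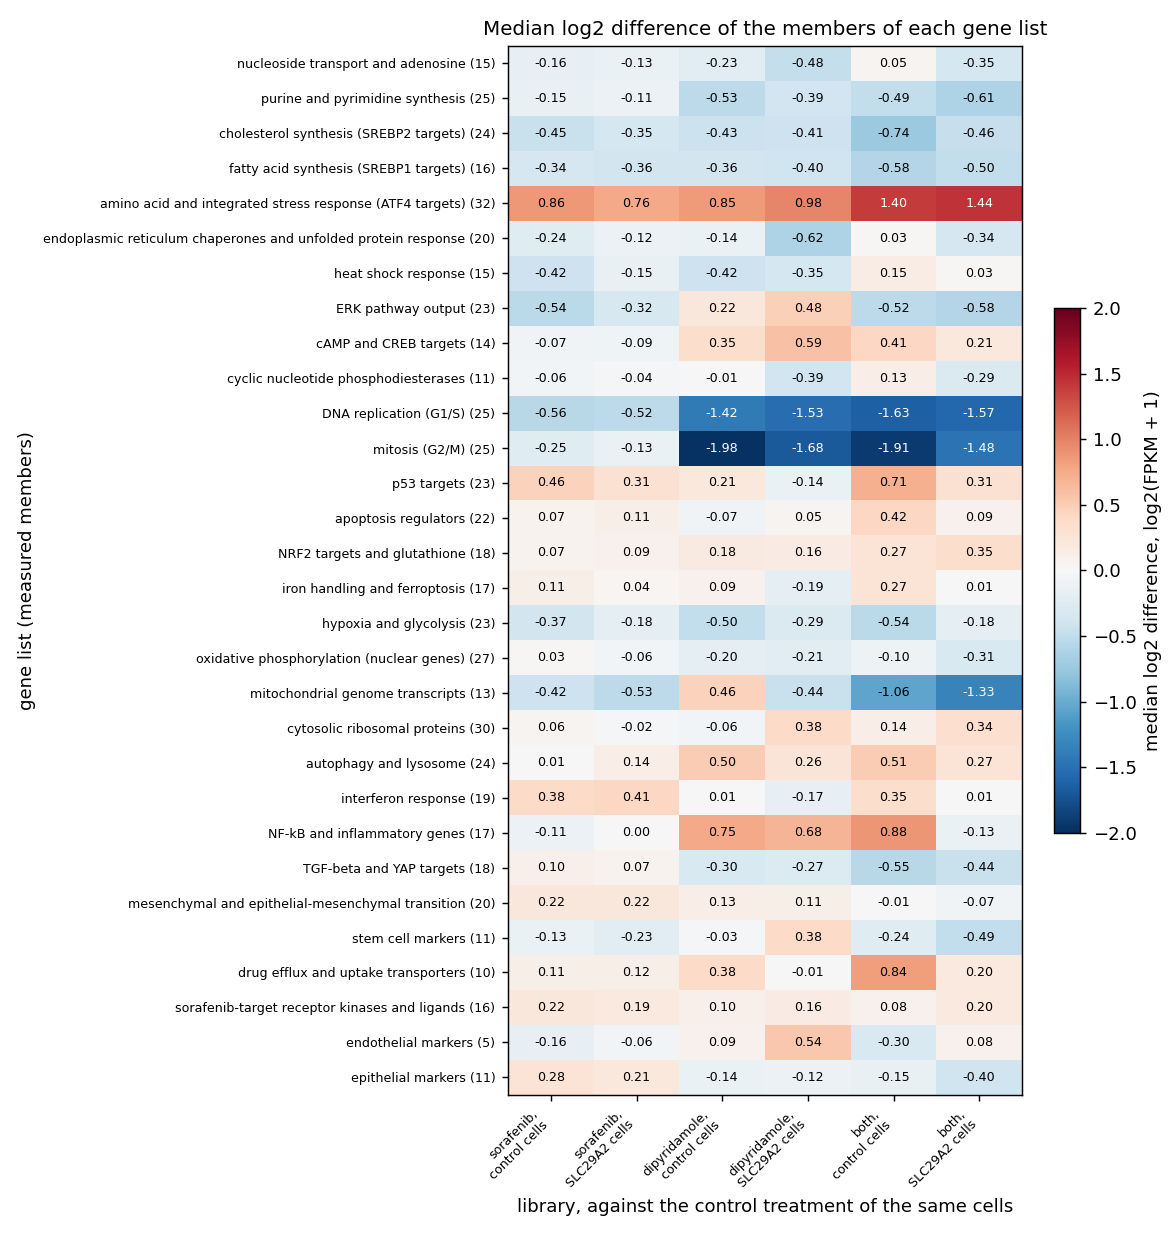
Median log2 difference of the measured members of each gene list in each treated library against the control treatment of the same cells, with 1 library per column. The mitosis medians were -1.98 and -1.68 with dipyridamole and -0.25 and -0.13 with sorafenib, in control and SLC29A2 cells.

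Whether ectopic SLC29A2 changed the response to dipyridamole or to sorafenib was tested as an interaction. For dipyridamole 0 genes passed in limma and 0 in voom, with 2756 genes at an unadjusted p under 0.05 against 695 that chance would give; 1 gene passed without the SLC29A2 cells given dipyridamole. The unadjusted count fell to 1670 without the control cells given the control treatment and to 1749 without the SLC29A2 cells given sorafenib. The smallest p-values, none of them past the threshold, belonged to MUC1, a mucin gene (-1.73 ± 0.17, adjusted p = 0.0817), LARP4B-DT, an antisense transcript (-5.15 ± 0.57, 0.102), SNORD1B on 9 reads or fewer (-2.97 ± 0.30, 0.0817), the methionine sulfoxide reductase gene MSRB1 (1.29 ± 0.17), C8orf82 (1.24 ± 0.17) and the elongation factor gene EEF1A2 (1.15 ± 0.16), with 0.106 for each of the last 3. LARP4B-DT stood at 0.147, 0.945, 41 and 49.2 FPKM (1, 6, 235 and 300 reads) in control cells with the control treatment, sorafenib, dipyridamole and both drugs, and at 5.27, 5.94, 7.59 and 2.83 FPKM (33, 35, 50 and 19 reads) in SLC29A2 cells. For sorafenib 0 genes passed in limma and 0 in voom, with 100 at an unadjusted p under 0.05 (28 in voom). The limma count was 157 without the control cells given the control treatment and 216 without those given sorafenib, and 186 and 435 without the SLC29A2 cells given the same. The genes of smallest p were small RNAs on 13 reads or fewer with an adjusted p of 1. Camera called 8 lists in each of these interactions, with 0 members past the threshold, and 0 of these calls held with an estimated correlation. In simulated data 14.9% and 11.9% of 2-fold interactions were recovered, so interactions of that size were mostly not detectable here.

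Whether the combination departed from the sum of the separate log2 effects was tested as the interaction of the drugs. Doses are not given in the sources used here, so the sum applies only if the combination used the doses of the single treatments. With limma 12 genes passed, 4 positive and 8 negative, each with an adjusted p of 0.0457, and 1839 had an unadjusted p under 0.05. That number fell to 1149 without the control cells given the control treatment, to 1204 without those given sorafenib and to 1075 without the SLC29A2 cells given sorafenib. ERFE, which encodes the iron hormone erythroferrone, stood at 10.8, 13.1, 15.4 and 76.1 FPKM in control cells with the control treatment, sorafenib, dipyridamole and both drugs, and at 9.15, 12.2, 16.8 and 75.9 FPKM in SLC29A2 cells (interaction 1.86 ± 0.19). The heat shock gene HSPA1B (2.01 ± 0.21) and ATP6V1FNB (2.87 ± 0.30) were also above the sum. The gene of the vasodilator peptide adrenomedullin, ADM, stood at 285.7, 224.7, 273.4 and 48.2 FPKM in control cells and 318.4, 246.3, 236.8 and 37.3 FPKM in SLC29A2 cells (-2.20 ± 0.23). The semaphorin receptor gene PLXNA2 (-2.32 ± 0.22), RGMB, which encodes a BMP co-receptor (-1.96 ± 0.19), its overlapping antisense gene RGMB-AS1 (-2.13 ± 0.24) and the small RNA SNORD46, on 7 to 40 reads (-2.58 ± 0.25), were below the sum, while MIR8078 (2.78 ± 0.31), on 14 reads or fewer, was above it. The other 3 were SLC6A9, ATP2B4 and WNT5B, given by values in the closing observations and chosen for naming after their values were seen. ATP6V1FNB (GRCh38 chromosome 7, 128866308 to 128872044, plus strand) lies within KCP on the other strand, so their reads cannot be told apart, and KCP had an interaction of 2.92 ± 0.34 that did not pass (0.0522).

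The count of 12 depended on the libraries and settings. It was at most 2 with a library left out (2 without the control cells given both drugs, 0 without any other), and each of the 9 genes named by the rule lost its call in every such refit. It was 0 with a pseudocount of 0.1, with no filter, with TPM and with no variance trend, 19 with size factors and 21 with voom. With size factors, HSPA1B (adjusted p = 0.0519) and ERFE (0.057) did not pass. The interactions of the 9 genes kept their sign with each library left out, for example -2.39 to -2.01 for ADM and 1.75 to 1.97 for ERFE.

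**Figure D4:**
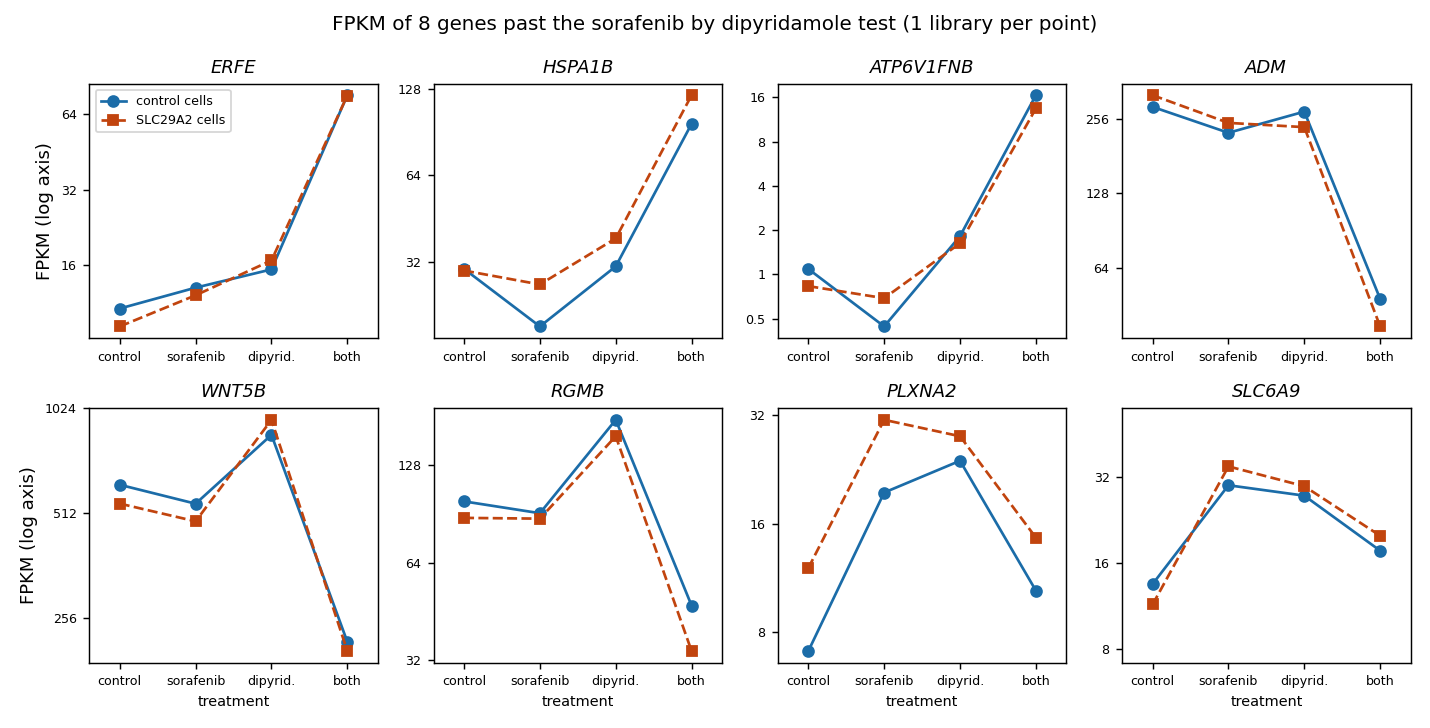
FPKM on a log axis of genes with an interaction of the drugs, by treatment, with control cells as circles and SLC29A2 cells as squares, and 1 library per point. ERFE stood at 76.1 and 75.9 FPKM with both drugs and at 9.15 to 16.8 FPKM in the other 6 libraries.

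Groups of genes departed from the sum in the same interaction, and 11 of 30 lists passed in camera, 4 upward and 7 downward. ATF4 targets lay below the sum (median interaction -0.52, adjusted p = 6.5e-11; adjusted p = 0.482 with an estimated correlation), with 0 members past the threshold (2 above and 13 below adjusted over the list alone). Their median difference from the control treatment was 0.86 with sorafenib, 0.85 with dipyridamole and 1.40 with both drugs in control cells, and 0.76, 0.98 and 1.44 in SLC29A2 cells. ERK output (median -0.54, adjusted p = 4.9e-08; adjusted p = 0.49 with an estimated correlation), with 1 above and 7 below adjusted over the list alone, was also below the sum. So were mitochondrial transcripts (-0.68, adjusted p = 2.5e-07; adjusted p = 0.542 with an estimated correlation; 1 below adjusted over the list alone). Their medians were -0.42, 0.46 and -1.06 in control cells and -0.53, -0.44 and -1.33 in SLC29A2 cells. Heat shock genes lay above the sum (median 0.47, adjusted p = 7.0e-05; adjusted p = 0.49 with an estimated correlation), with HSPA1B past the threshold and 6 above adjusted over the list alone. Of the 11 calls 7 held with each library left out.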

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

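Of the tests in this part, the comparison of protein-coding with other genes, the size-factor count of small p-values, the ATF4 target tests, the covariance of the drug effects and their correlation from separate libraries were chosen after the results were seen. Where the libraries were split in other ways, several splits gave identical counts of genes and lists, so the splits counted below are not all separate tests. Each other split also follows a factor or an interaction, in whole or in part. Its counts of genes and lists can therefore hold real effects and are not those of chance alone.

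The interaction of the drugs drew attention through its own test, in which the effect of 1 drug differed with the other drug. The 12 genes were ATP6V1FNB (2.87), MIR8078 (2.78), HSPA1B (2.01) and ERFE (1.86) above the sum of the log2 effects, and SNORD46 (-2.58), PLXNA2 (-2.32), ADM (-2.2), RGMB-AS1 (-2.13), RGMB (-1.96), WNT5B (-1.91), SLC6A9 (-1.9) and ATP2B4 (-1.56) below it. WNT5B, which encodes a WNT ligand, SLC6A9, a glycine transporter gene, and ATP2B4, a calcium pump gene, lie outside the naming rule and were chosen after their values were seen. WNT5B stood at 618, 545.3, 859.8 and 218.7 FPKM in control cells with the control treatment, sorafenib, dipyridamole and both drugs, and at 545.6, 485.3, 949.7 and 205.7 FPKM in SLC29A2 cells. ATP2B4 stood at 38.3, 77.3, 77.9 and 48.2 FPKM in control cells and 39.9, 75.8, 84.3 and 58.1 FPKM in SLC29A2 cells, so each drug alone went with a higher level than both drugs. Of 32 splits of the libraries, 1, the real one, gave 12 genes, and the highest of the others gave 1. The interaction itself stays at least partly in the error of those others, which lowers their counts, although some also follow it in part. Interactions of the genes named by the rule kept their sign with each library left out, such as -2.13 to -1.8 for RGMB and 2.66 to 3.08 for ATP6V1FNB. No gene named by the rule kept its call with any library left out; the highest adjusted p was 0.313 to 0.321, without the SLC29A2 cells given dipyridamole.

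Lists passed the same interaction test through camera. Besides ATF4 targets (-0.52), ERK output (-0.54), mitochondrial transcripts (-0.68) and heat shock genes (0.47), given in the report, these were NF-kB genes (-0.57, adjusted p = 1.6e-05; adjusted p = 0.49 with an estimated correlation), mesenchymal genes (-0.39, 9.5e-05; 0.49) and TGF-beta and YAP targets (-0.31, 9.5e-05; 0.482). Mitosis (0.39, 2.3e-04; 0.709), DNA replication (0.33, 0.00421; 0.49), endoplasmic reticulum chaperones (0.38, 0.0095; 0.782) and receptor kinases and ligands (-0.16, 0.0476; 0.49) followed. The last 4 lost their calls with a library left out: mitosis without the SLC29A2 cells given both drugs (0.256), replication (0.0972) and chaperones (0.203) without those given dipyridamole, and receptor kinases without the control cells given dipyridamole (0.22). Of 32 splits 6 gave at least 11 lists, and the highest of the others gave 13, so chance is not excluded for the number of lists.

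Lists also passed the tests of cell type against each drug. With dipyridamole these were ribosomal proteins (0.33, adjusted p = 1.1e-07; adjusted p = 0.802 with an estimated correlation), ATF4 targets (0.32, 0.00224; 0.836), mitosis (0.21, 0.00172; 0.836), cholesterol synthesis (0.17, 0.0117; 0.802), fatty acid synthesis (0.14, 0.0329; 0.802), hypoxia and glycolysis (0.12, 0.0247; 0.811), endoplasmic reticulum chaperones (-0.46, 0.0117; 0.836) and transporters (-0.51, 0.0325; 0.802). Only the ribosomal proteins kept the call with each library left out. With sorafenib they were mitochondrial transcripts (0.31, 5.8e-05), mitosis (0.2, 8.8e-07), hypoxia (0.13, 0.0196), DNA replication (0.12, 0.0328), oxidative phosphorylation (-0.14, 0.0149), NF-kB genes (-0.18, 0.0416), ribosomal proteins (-0.19, 0.0013) and cAMP targets (-0.25, 0.0451), each with an adjusted p of 0.848 with an estimated correlation, and none kept its call with each library left out. In each of these interactions 14 of 32 splits gave at least 8 lists, with 13 in the highest of the others, so chance is not excluded for the number of lists. Since 0 genes passed in limma, all 32 splits gave at least as many genes by construction, with 12 in the highest of the others, and this count decides nothing.

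For the main effects, 1 of 33 splits, the real one, gave as many genes for sorafenib (1127) and for dipyridamole (4173), with 0 genes in the highest of the others each time. In those other splits the effect of the drug itself stays at least partly in the error and lowers their counts, although some also follow it in part. The comparison therefore does not by itself exclude chance. For cell type 3 of 33 splits gave at least 1 gene, and the split that follows the product of the drugs, which is their interaction, gave 22. The number of lists is not separated from chance: 22 of 33 splits gave at least 7 lists as cell type did (13 in the highest of the others), 14 gave at least 12 as sorafenib did (16) and 8 gave at least 11 as dipyridamole did (14).

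The interaction of cell type with dipyridamole had 2756 genes of 13899 at an unadjusted p under 0.05, 3.97 times the number chance would give, although 0 passed in limma. Only 1 of 32 splits, the real one, gave as many, and the highest of the others gave 2607. In those others the interaction stays at least partly in the error, which lowers their counts. The splits that gave 2607 also follow this interaction in part, which can raise theirs, so 2607 is not a measure of chance. Several splits gave identical counts, so the comparison does not by itself exclude chance. The number fell to 1670 without the control cells given the control treatment and to 1749 without the SLC29A2 cells given sorafenib. Dividing out size factors left 2958 genes, and taking out a trend on transcript length and GC content left 2387 of 13874, which argues against either as the whole cause. Among protein-coding genes 2203 of 11637 remained (3.79 times), so extra non-coding RNA in the dipyridamole-treated control cells could account for only part, although the other genes were richer in small p-values (553 of 2262, 4.89 times, median -0.47). An effect of ectopic SLC29A2 on the response remains a candidate explanation that cannot be told apart from differences between single libraries, with 1 library per condition.

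ATF4 targets lay below the sum of the log2 effects with both drugs in camera (adjusted p = 6.5e-11), with 0 members past the threshold; adjusted p = 0.482 with an estimated correlation. Against the sum on the linear scale, their median log2 ratio was -0.2 in control cells (22 of 32 below; quartiles -0.55 and 0.04) and -0.19 in SLC29A2 cells (21 of 32 below; quartiles -0.58 and 0.19), where the log scale gave -0.53 and -0.64. Addition on the linear scale was to be set aside only if both medians lay below -0.2, and they did not. Simple addition read on a log scale therefore cannot be told apart from a ceiling of the response. The linear comparison was made without size factors, which stood at 1.207 for control cells given both drugs. With size factors divided out the median interaction on the log scale was -0.65, which argues against a shift of scale between libraries.

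In the main effects, which include the libraries given both drugs, sorafenib and dipyridamole changed genes in the same direction more often than independent lists would. With size factors divided out, shared calls were 3.93 times those of independent lists for higher genes and 3.39 times for lower genes, which argues against a shift of scale. The covariance of the effects was 0.0788, but the design makes independent error nearly cancel in it, so it decides nothing about error shared through common libraries. The effects of each drug alone, taken from separate libraries, correlated at 0.363 (sorafenib in control cells, dipyridamole in SLC29A2 cells) and 0.316 (the reverse). The bound set for them was the highest of the 6 correlations between pairs of libraries that differed in cell type, 0.435 (median -0.089, lowest -0.23). No library was common to the effects correlated, so libraries in common cannot have produced these values. Neither value passes the bound, so a shared response to the drugs and other shared structure of the libraries cannot be told apart.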

How the results depend on the processing

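Of the alternatives, voom, leaving out gene models under 200 nt and leaving out both dipyridamole-treated control-cell libraries were chosen after the data were seen, as were size factors for the library pairs between cell types given a drug and between both drugs and 1 drug, and the choice to follow single genes only where they were called or always named. In each refit with 1 library left out, the remaining library of a pair was assumed to vary like the others. Each condition had 1 library, and small RNAs had few reads at totals of 14.07 to 16.69 M reads. The libraries were selected by poly(A) tail, so those few reads cannot be put down to depth alone. These limits concern replication, depth and library type. The interactions were not refitted in the models with all pairwise interactions or 4 treatments, or without both dipyridamole-treated control-cell libraries.

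For sorafenib, 136 genes passed with no filter on low values, 4839 with all pairwise interactions, 1755 with 4 treatments, 301 without both dipyridamole-treated control-cell libraries and 272 to 914 with each library left out; fewer libraries and more genes tested apply to some of these by construction, and otherwise the cause was not tested. For dipyridamole the counts were 2622 with no filter, 7411 with all pairwise interactions and 2926 to 3641 with each library left out. Cell type gave 1 to 2 genes with each library left out, its interaction with dipyridamole 0 to 1 and with sorafenib 0 to 0. The interaction of the drugs gave 0 genes with a pseudocount of 0.1, 0 with no filter, 0 with TPM, 0 with no variance trend, 19 with size factors, 21 with voom and 0 to 2 with each library left out; the cause was not tested. Size factors moved the median of all genes from 0.089 to -0.019 for sorafenib, from -0.139 to 0.044 for cell type by dipyridamole and from 0.105 to -0.012 for the interaction of the drugs.

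With an estimated correlation camera called 0 lists for cell type, 0 for sorafenib, 0 for dipyridamole and 0 for each interaction. For purine and pyrimidine synthesis with dipyridamole the estimate was 0.007, below the preset 0.01. Its camera adjusted p still went from 1.2e-07 to 0.126, so the lost calls cannot all be put down to correlation between genes. With size factors it called 4 lists for cell type. With each library left out it called 4 to 9 lists for cell type, 12 to 15 for sorafenib, 9 to 12 for dipyridamole, 5 to 10 for cell type by dipyridamole, 3 to 10 for cell type by sorafenib and 10 to 11 for the interaction of the drugs. The lowest counts of 5 and 3 came without the SLC29A2 cells given both drugs, and 3 also came without the control cells given sorafenib.

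With a pseudocount of 0.1, genes at least 2-fold apart from the control treatment numbered 769 with sorafenib and 1895 with dipyridamole in control cells, 722 and 1954 in SLC29A2 cells, and 472 between the cell types. With a minimum of 5 FPKM they numbered 177 with sorafenib, 786 with dipyridamole and 1741 with both drugs in control cells, 144 with sorafenib in SLC29A2 cells, and 33 between the cell types; fewer genes were counted by construction.

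No called gene that is named changed sign under any alternative. Genes of the nucleoside list that had not passed did change sign. For cell type with size factors SLC29A3 was at 0.02, ADORA1 0.04, NT5E 0.04, ENTPD1 0.01, ADK 0.07 and CDA 0.01, and without both dipyridamole-treated control-cell libraries ADORA1 was at 0.03, NT5E 0.29, ENTPD1 0.16, DCK 0.17, TK1 -0.3 and TK2 0.07. For sorafenib ENTPD1 was at -0.04 and TK1 at -0.05 with size factors, and ENTPD1 at -0.05 and DCK at -0.04 without those libraries. For dipyridamole without them SLC29A3 was at 0.01 and ADA at 0.1. The cause was not tested.

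With each library left out, the ranges for cell type were -0.13 to 0.04 for SLC29A3, -0.16 to 0.12 for ADORA1, -0.3 to 0.18 for NT5E, -0.22 to 0.07 for ENTPD1, -0.05 to 0.01 for ADK, -0.29 to 0.09 for CDA, -0.04 to 0.17 for PNP, -0.3 to 0.02 for SLC29A4, 0 to 0.23 for ADORA2B, -0.29 to 0.14 for DCK, -0.02 to 0.51 for TK1 and -0.38 to -0.05 for TK2. For sorafenib they were -0.08 to 0.21 for ENTPD1, -0.22 to 0.31 for TK1, -0.02 to 0.3 for SLC29A4 and -0.05 to 0.38 for DCK, and for dipyridamole -0.2 to 0.2 for SLC29A2, -0.1 to 0.08 for SLC29A3 and -0.17 to 0.03 for ADA. Lists turned as well: for cell type the camera adjusted p ran from 1.1e-13 to 0.987 for mitochondrial transcripts and 3.4e-08 to 0.952 for mitosis. For cell type by sorafenib it ran from 9.8e-05 to 0.989 for hypoxia, 7.9e-08 to 0.989 for NF-kB genes, 4.0e-19 to 0.632 for mitochondrial transcripts, 1.0e-07 to 0.907 for ribosomal proteins and 7.5e-13 to 0.815 for mitosis. Among other named genes that had not passed, the sign changed under at least 1 alternative for 20 of 119 for cell type, 2 of 48 for sorafenib, 2 of 17 for dipyridamole, 10 of 131 for cell type by dipyridamole, 54 of 133 for cell type by sorafenib and 7 of 132 for the interaction of the drugs.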

Other observations

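This part adds no test; which members of the fixed lists it describes was chosen after the results were seen. Some genes of iron storage and antioxidant defence rose with dipyridamole, although neither of their lists passed. The ferritin light chain gene FTL rose from 1290 to 3516 FPKM (1.42 ± 0.17 SE, n = 4 pairs, limma adjusted p = 6.1e-04), the heavy chain gene FTH1 rose by 1.08 ± 0.14 (7.7e-04) and HMOX1, which encodes heme oxygenase, rose from 28.5 to 135.7 FPKM (2.18 ± 0.17, 8.1e-05). AIFM2, a ferroptosis suppressor gene, rose by 0.65 on the log2 scale. Of 18 NRF2 targets 6 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.268), and of 17 iron and ferroptosis genes 6 rose and 3 fell (7 and 6 adjusted over the list alone; camera adjusted p = 0.966; median -0.03, mean 0.2). Without the control cells given sorafenib 1 iron gene fell, with size factors 5 rose and 6 fell, and without those given the control treatment 0 NRF2 targets fell.

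Keratin genes KRT18 (629.5 to 169.6 FPKM, -1.87 ± 0.12, 4.7e-05) and KRT8 (1673 to 661.5 FPKM, -1.36 ± 0.18, 8.2e-04) fell with dipyridamole. Of 11 cyclic nucleotide phosphodiesterase genes, a family in which dipyridamole inhibits some products, 1 rose and 3 fell (1 and 3 adjusted over the list alone, camera adjusted p = 0.42). PDE2A rose by 1.09 ± 0.18, and PDE3B (-0.71 ± 0.15), PDE1C (-0.63 ± 0.14) and PDE4A (-0.54 ± 0.17) fell. PDE4A lost its call in each refit with a library left out, with a highest adjusted p of 0.116 without the SLC29A2 cells given the control treatment, and lost it without both dipyridamole-treated control-cell libraries (0.0772).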
